A study of Spodoptera frugiperda and Homo sapiens with 2 samples.

How the data were processed

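RNA was sequenced from 2 purified membrane protein preparations, each represented by 1 library. The first was the proton-activated chloride channel (PAC) of the frog Xenopus tropicalis (xPAC), produced with a baculovirus in Sf9 cells, an ovarian cell line of the moth Spodoptera frugiperda. The second was the human channel (hPAC), produced by transient transfection of HEK293F cells, a suspension line derived from human embryonic kidney. Per the labels' protocols, both were harvested after 60 hours of expression, at 27 °C for Sf9 and 37 °C for HEK293F. Membranes were solubilised in 2% DDM and the channel was captured on Strep-tactin resin. The wash buffer held 0.06% digitonin for xPAC and 0.05% DDM for hPAC. Co-purified RNA was recovered with phenol-chloroform, demethylated, partly hydrolysed and made into small RNA libraries. Hydrolysis cuts each tRNA into fragments, so a read is a fragment and not a molecule. Demethylation removes base modifications that stop reverse transcription, and any modification that remains can lower the reads of a tRNA.

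The submitters' processing notes name FastQC 0.11.8, STAR 2.7.1a, HTSeq 0.11.2 and BWA 0.7.17-r1198 and the human build GRCh38, without their roles. The insect assembly is not given in the sources used here, and how reads with several equal matches were placed is likewise not given. For xPAC the authors deposited a count of reads per gene and an FPKM value, per the file headers. All listed xPAC counts were above 10. The deposited FPKM values used the listed genomic width of a gene and a denominator equal to the sum of the listed counts, 1174485, as computed from the values. FPKM was used only for this check. For hPAC the authors deposited only RPKM values, per the file headers.

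Reads behind the hPAC RPKM values were recovered from their steps. RPKM times gene length gave multiples of 0.632 RPM, the worth of 1 read, which implies a denominator of 1581740 reads. Of the 438 listed hPAC tRNA genes, 89.0% came out within 0.01 of a whole number of reads, and 99.1% within that tolerance of a whole number or a simple fraction with a denominator of at most 10. For 25 tRNA genes longer than a mature tRNA, a shorter length in the range of mature tRNAs gave whole reads and was used. Several lengths were tried for each gene, before the listed width, so some matches may be accidental. For 2 further genes, TRL-CAA1-1 and TRL-CAA1-2, a length of 84 nt was assumed. The 27 tRNA genes given a shorter length held 1.39% of the denominator. For 240 other features, mostly protein-coding genes and lncRNAs, the listed genomic width did not give whole reads within 0.001, so only their RPKM is reported. They and unlisted features make up 20.1% of the denominator. The recovery was tested on 5 simulated hPAC libraries of at least 431 tRNA genes. It returned the reads of at least 99.3% of tRNA genes, and the tRNA share to within 0.00493 percentage points. The simulated libraries held whole reads only and the lengths that the recovery had chosen. Their accuracy therefore does not cover fractional reads or wrongly chosen lengths in the real table.

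Shares were computed from the deposited counts (xPAC) and the recovered reads (hPAC), with exact Clopper-Pearson 95% binomial intervals. These intervals cover counting error only and take reads as independent. Reads amplified by PCR or cut from the same molecule are not independent, so the intervals may be too narrow even for that error. Each group had 1 library, so no test between conditions was made and no p-value is given for any difference between libraries. The design of the comparison, the tRNA lists and the rule for named items were set before the data were examined. That design took both tables for counts and the sum of listed features as the denominator; for hPAC the denominator of the authors' RPKM values was used in its place, because the reads of 240 features could not be recovered. It also counted mitochondrial tRNA in every share, which was kept for amino acids, but mitochondrial gene names carry no anticodon. The rule named the 10 most abundant features, tRNA genes and anticodons per library, the 10 anticodons with the largest ratio of tRNA shares in each direction among those with at least 10 reads in both libraries, and every amino acid. Reads were summed over gene copies, because many tRNA genes have identical sequences. Amino acids were taken from the deposited columns and anticodons from the gene names. In xPAC the anticodon was found in the deposited sequence of 307 of 307 tRNA genes. Initiator tRNA was identified by name in hPAC and in xPAC by the anticodon stem-loop of eukaryotic initiator tRNAs, with C or U before the anticodon. Shares per amino acid included mitochondrial tRNA, and shares per anticodon covered nuclear genes only. List medians of log2 ratios were placed among 10000 random lists of the same size matched on mean abundance in 3 bins. The effective number of anticodons is the exponential of the Shannon entropy, with an interval from 1000 multinomial resamples.

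Alternatives covered the denominator, a minimum of 10 reads, the dominant features, gene copies, edgeR 4.0.16 TMM scaling and DESeq2 1.42.0 median-of-ratios scaling over anticodons. Both scalings were only used as library factors. The alternatives of a length at the listed width, of recovered genes alone, of rRNA left out with its neighbouring pseudogene, of anticodons per gene copy and of unlisted anticodons at 0 were added after seeing the data. Python 3.11.15, SciPy 1.17.1 and R 4.3.3 were used. Spodoptera genes outside the tRNAs carry only database numbers as names, so few are named. A gene table of another Spodoptera assembly was not used. The cells' total RNA, a mock purification and an unrelated membrane protein were not analysed here, so no share is measured against a background.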

Results

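The kinds of RNA that stayed with the purified channels were profiled by small RNA sequencing after partial hydrolysis, in 1 xPAC library from Sf9 insect cells and 1 hPAC library from HEK293F human cells. The study's title names transfer RNA as an inhibitor of the channel, and the profiles list which RNAs, and which tRNAs among them, came along with each protein. The xPAC library held 1174485 reads over 868 listed genes, of which 307 were tRNA genes. The hPAC library held a denominator of 1581740 reads and 1064 listed genes, of which 438 were tRNA genes. The libraries have no replicates, and they differ in channel species, host cell, temperature and wash detergent at once.

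Transfer RNA was the most abundant class in both libraries. It took 50.4% of xPAC reads (95% interval 50.3 to 50.5; 591979 reads) and 77.3% of hPAC reads (77.2 to 77.3; 1222230 reads). Ribosomal RNA, the structural RNA of ribosomes, took 34.3% of xPAC reads over 68 genes and 0.680% of hPAC reads over 56 genes. A further 10.9% of xPAC reads fell on a single gene annotated as a pseudogene, LOC118279434 (chromosome 27, 1208383 to 1214321), which lies next to annotated rRNA genes on the same strand. That locus as a whole, with 8 features, held 27.2% of xPAC reads. The 57 rRNA genes between 110 and 130 nt long, the size of 5S rRNA, held another 16.2%, led by LOC118274414 (chromosome 19, 4003645 to 4003763) with 112194 reads. Protein-coding genes held 2.32% of xPAC reads, and snoRNAs, which guide rRNA modification, held 1.32% in xPAC and 0.746% in hPAC. Genes annotated as transcribed pseudogenes held 0.655% of hPAC reads, close to the rRNA share. Nearly all of these reads fell on LOC124905563 (5198 reads) and LOC124905554 (5160 reads). The denominators differ, since the xPAC total covers listed genes only and 20.1% of the hPAC total lies in genes whose reads were not resolved or not listed. Part of that 20.1% may be tRNA reads. The unresolved genes LOC107986586, PRMT5-DT, LOC101060170, LINC00324 and OR1F1, all of high RPKM, each overlap at least 1 listed tRNA gene on the same strand. How much of it is tRNA cannot be read from the deposited values. With rRNA left out, the tRNA share was 76.7% in xPAC and 77.8% in hPAC. Under settings chosen after the data were seen, it was 91.9% in xPAC without rRNA and LOC118279434, and 96.7% in hPAC over the genes with recovered reads. These shares rest on unlike denominators and cannot be compared. The hPAC setting kept all 438 tRNA genes but only 13 of 210 protein-coding genes, which raises its share, while xPAC kept all 450 protein-coding genes.

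In the xPAC library, tRNAs for aspartate, glutamine, lysine and glutamate together held 69.1% of all tRNA reads. Asp-GUC alone took 26.7% (26.6 to 26.8) and Gln-CUG 15.1% (15.0 to 15.2), followed by Lys-UUU with 7.66%, Gln-UUG with 6.13%, Glu-UUC with 5.72%, Lys-CUU with 3.94%, Glu-CUC with 3.88%, Arg-ACG with 3.56%, Pro-CGG with 3.07% and Gly-GCC with 2.88%. By amino acid, tRNA-Asp held 26.7%, tRNA-Gln 21.2%, tRNA-Lys 11.6%, tRNA-Glu 9.60%, tRNA-Arg 7.26% and tRNA-Pro 7.23%. Without the gene listed with the most reads, which holds most reads of a sequence shared by 11 identical Asp-GUC copies, tRNA-Asp held 14.7% and tRNA-Gln 24.7%. As means per listed gene copy, tRNA-Asp held 24.4%, tRNA-Gln 22.5%, tRNA-Lys 7.65%, tRNA-Glu 6.34%, tRNA-Pro 5.54% and tRNA-Arg 4.79%. At the other end, tRNA-His held 0.170%, tRNA-Ser 0.215%, tRNA-Met 0.323%, tRNA-Asn 0.525%, tRNA-Trp 0.575% and tRNA-Leu 0.798%. The remaining amino acids lay between, from tRNA-Tyr (0.852%), tRNA-Val (1.04%) and tRNA-Ala (1.14%) through tRNA-Ile (1.47%), tRNA-Phe (1.62%) and tRNA-Thr (1.82%) to tRNA-Cys (2.38%) and tRNA-Gly (3.46%). The effective number of anticodons was 15.4 (15.3 to 15.4) among 47 listed.

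The most abundant xPAC tRNA sequence was an Asp-GUC gene of 72 nt with 90494 reads over 11 identical copies, 15.3% of tRNA reads. Its sequence is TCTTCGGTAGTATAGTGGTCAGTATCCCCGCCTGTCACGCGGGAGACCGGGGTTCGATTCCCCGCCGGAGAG. The second, also Asp-GUC, had 65562 reads over 7 copies and differs from the first by 1 substitution, C20A, counted from the 5′ end of the gene. Reads were very unevenly divided among identical xPAC copies. Trnad-guc-7 (chromosome 10, 11858699 to 11858770, minus strand) was listed with 83730 of the 90494 reads, and the median copy of that sequence with 34. Over the 53 sets of identical xPAC genes, the top copy held a median of 90.4% of the reads of its set, 2.77 times an even share. In the 54 hPAC families of equally named copies, the median was 38.9%, 1.05 times an even share, with a maximum of 4.04 times in TRF-GAA1. Reads of identical copies cannot be told apart, so copies were summed.

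In the hPAC library, tRNAs for glutamate, proline, arginine and glycine led, with 61.5% of tRNA reads together. The tRNA-Glu share was 22.0% (21.9 to 22.1), tRNA-Pro 16.0%, tRNA-Arg 14.5%, tRNA-Gly 9.00%, tRNA-Asp 6.87%, tRNA-Lys 6.30% and tRNA-His 5.81%. The leading anticodons, as shares of nuclear tRNA reads, were Glu-CUC at 12.9%, Glu-UUC at 7.99%, Gly-GCC at 7.20%, Asp-GUC at 7.03%, Pro-UGG at 6.69%, Lys-CUU at 6.00%, His-GUG at 5.78%, Arg-CCG at 4.91%, Pro-CGG at 4.88% and Arg-UCG at 4.41%. The lowest shares were those of tRNA-Ile (0.259%), tRNA-SeC (0.319%), tRNA-Ala (0.385%), tRNA-Phe (0.477%) and tRNA-Tyr (0.722%). The other amino acids held 1.05% (tRNA-Cys), 1.31% (tRNA-Trp), 1.51% (tRNA-Met), 1.61% (tRNA-Thr), 1.85% (tRNA-Asn), 1.94% (tRNA-Leu), 2.13% (tRNA-Val), 2.51% (tRNA-Ser) and 3.46% (tRNA-Gln). The hPAC pool was spread over more tRNAs, with an effective number of 23.4 anticodons (23.4 to 23.4) among 47 listed. Summed over equally named copies, the family TRE-CTC1 led with 138709 reads over 7 genes, followed by TRD-GTC2 with 72894 reads over 11. The order of single genes holds only as the authors' processing placed reads among copies. The single gene listed with the most reads, TRE-TTC2-1 (GRCh38 chromosome 13, 44917927 to 44917998, minus strand), held 39983 reads, 3.27% of tRNA reads. It was followed by TRR-CCG2-1 (chromosome 17, 68019897 to 68019969, minus strand) with 37543 reads and TRE-TTC2-2 (chromosome 15, 26082234 to 26082305, minus strand) with 25432 reads.

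**Figure D1:**
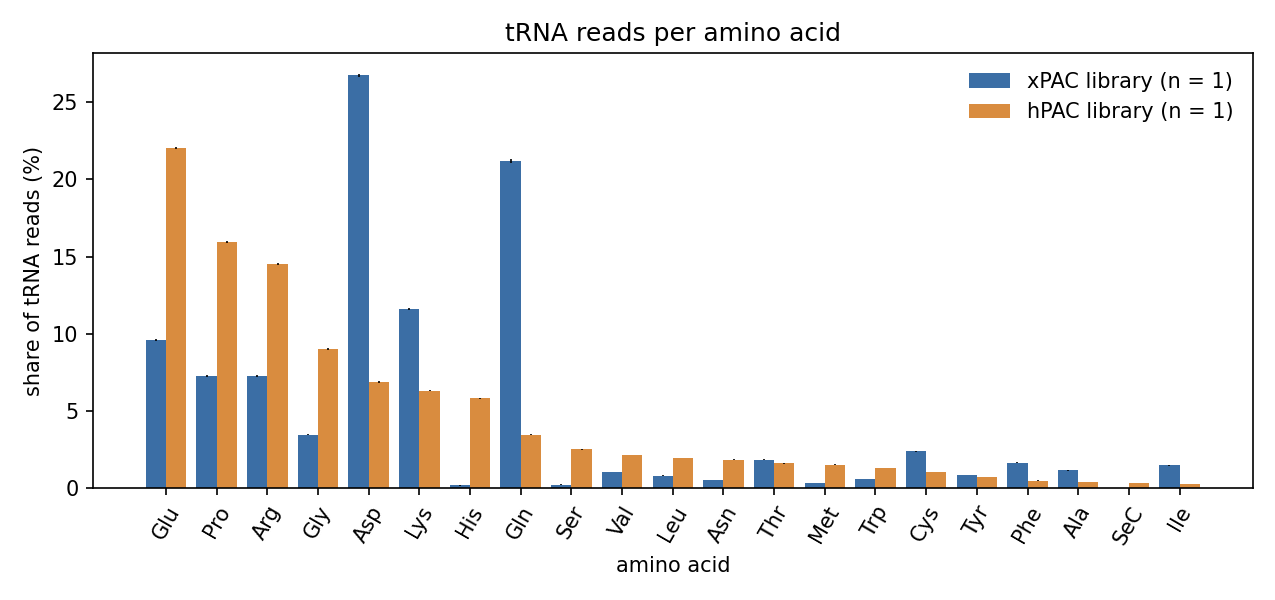
Share of tRNA reads (%) per amino acid in the xPAC and hPAC libraries, 1 library each, ordered by the hPAC share. Error bars are exact 95% intervals for counting error. Asp and Gln stand out in xPAC at 26.7% and 21.2%, and Glu, Pro and Arg in hPAC at 22.0%, 16.0% and 14.5%.

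Set side by side, the libraries shared a broad order of anticodons but differed widely for single ones. Across the 44 anticodons listed in both, the log2 shares had a Pearson correlation of 0.556 and a Spearman correlation of 0.535, and without the 2 anticodons farthest from the xPAC median these were 0.506 and 0.488. Anticodons are not independent replicates, and no p-value is attached. Asp-GUC, Glu-UUC, Glu-CUC, Lys-CUU, Pro-CGG and Gly-GCC were among the 10 most abundant anticodons of both libraries. With 1 library per group, a ratio of shares compares these libraries and not the channels, and its interval covers counting error only.

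Lysine and glutamine tRNAs with a U at the wobble position were the furthest towards xPAC. Lys-UUU held 7.66% of xPAC and 0.445% of hPAC nuclear tRNA reads, a 17.2-fold higher share in xPAC (log2 ratio of hPAC over xPAC -4.11, interval -4.15 to -4.07). Gln-UUG held 6.13% and 0.357%, also 17.2-fold higher in xPAC (-4.10). Next came Ile-UAU with 6.65-fold, Ala-CGC with 6.13-fold, Ile-AAU with 5.16-fold, Gln-CUG with 4.77-fold, Leu-UAA with 4.16-fold, Asp-GUC with 3.80-fold, Gly-UCC with 3.70-fold and Phe-GAA with 3.44-fold higher shares in xPAC. The sister anticodon Lys-CUU held 3.94% and 6.00%, a log2 ratio of 0.61 whose sign turned under both other scalings described below.

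Histidine and serine tRNAs were the furthest towards hPAC. His-GUG held 5.78% of hPAC and 0.170% of xPAC reads, a 33.9-fold higher share in hPAC (log2 ratio 5.08, interval 4.99 to 5.17). Ser-GCU held 1.71% and 0.0535%, a 32.0-fold higher share (5.00, interval 4.84 to 5.16). Next came Ser-UGA with 15.5-fold, Gly-CCC with 14.3-fold, Leu-UAG with 10.5-fold, Asn-GUU with 5.39-fold, Leu-AAG with 5.24-fold, Leu-CAA with 5.22-fold, Thr-CGU with 5.19-fold and Met-CAU with 4.77-fold higher shares in hPAC. The Met-CAU ratio compares unlike sets, since 5379 of its hPAC reads came from initiator genes and none was found in xPAC. The other nuclear Met genes held 1.06% of hPAC and 0.323% of xPAC tRNA reads. Arg-CCG, with 4.91% of hPAC reads, SeC-UCA, with 0.326%, and Ile-GAU, with 1 read, were not listed in xPAC. Asn-AUU, Arg-GCG and Leu-GAG were listed in xPAC with 1035, 2091 and 199 reads and not in hPAC. Of the 44 shared anticodons, 29 had a higher share in hPAC and 15 in xPAC, 22 and 12 of them by more than 2-fold. Scaling by TMM or by the median of ratios instead of the tRNA total shifted every log2 ratio by -0.76 or -0.89 and gave an even split of 22 and 22, with 13 and 14 (TMM) or 12 and 15 (median of ratios) beyond 2-fold. Median-of-ratios scaling centres the shared anticodons on their median, so its even split follows from the method. TMM is likewise set from a trimmed mean of the ratios of these same anticodons, so its split is not an independent check.

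**Figure D2:**
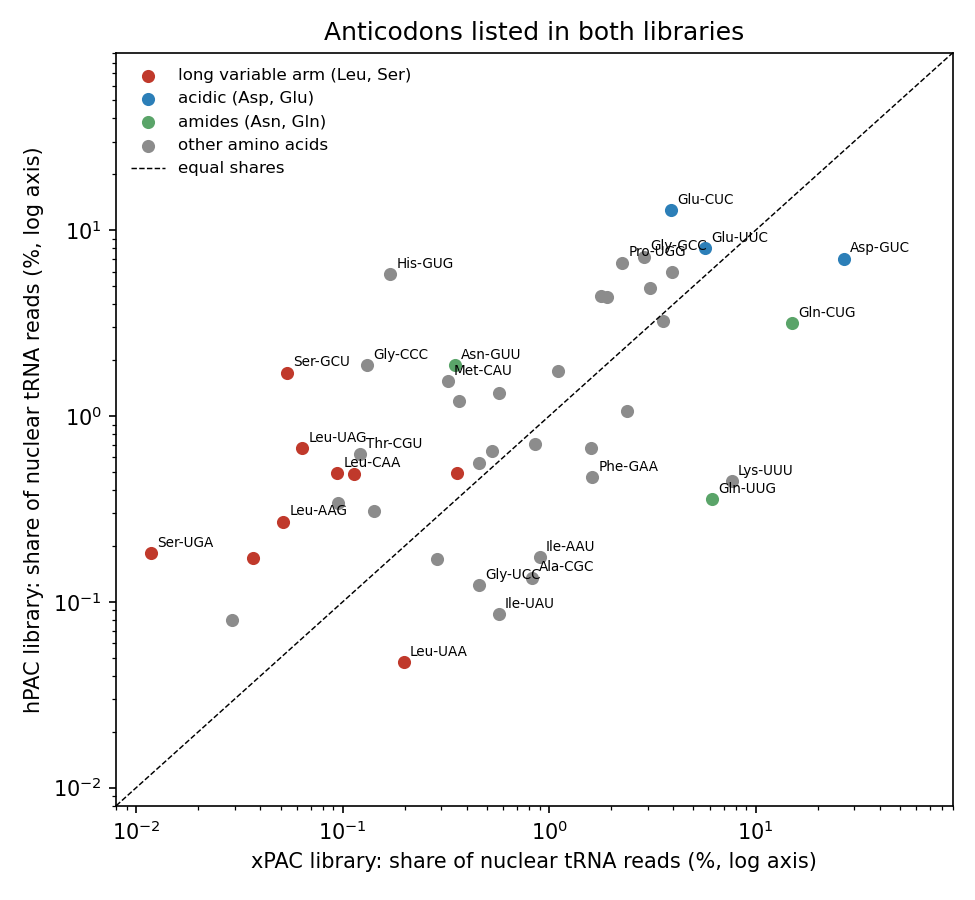
Share of nuclear tRNA reads (%) of each of the 44 shared anticodons in xPAC (horizontal) and hPAC (vertical), both on log axes, with 1 library each; the dashed line marks equal shares. Lys-UUU and Gln-UUG lie farthest below the line, and His-GUG and Ser-GCU farthest above it.

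Several groups of tRNAs fixed beforehand were compared as lists. The tRNAs with a long variable arm, those for leucine, serine and selenocysteine, held little of either pool, 1.01% of xPAC tRNA reads (0.988 to 1.04) and 4.77% of hPAC tRNA reads (4.73 to 4.81). They made up 8.47% and 14.4% of the listed tRNA genes. The list was drawn by amino acid. In hPAC it therefore also held the mitochondrial tRNA-Leu and tRNA-Ser genes, with 228 and 170 reads. These are 59 to 75 nt long, shorter than tRNAs with a long variable arm. Shares of listed genes and means per listed copy also depend on what was listed. The lowest listed tRNA gene had 11 reads in xPAC and 0.5 in hPAC, and xPAC reads were unevenly placed among identical copies. An order of the libraries per listed copy is therefore a description of unlike lists. Of the 9 shared anticodons of the long variable arm list, 8 had a higher share in hPAC, with a median log2 ratio of 2.38, above 99.3% of matched random lists, and 7 of the 9 did so under TMM or median-of-ratios scaling. All 9 belong to Leu or Ser, while the random lists draw each anticodon separately. The percentile may therefore overstate how unusual the list is. Acidic amino acids, Asp and Glu, held 36.3% of xPAC and 28.9% of hPAC tRNA reads, with 2 of 3 anticodons higher in hPAC on tRNA totals and 1 of 3 under either other scaling. As means per listed gene copy the order turned, to 30.7% in xPAC and 33.8% in hPAC. The amides Asn and Gln held 21.7% and 5.31%, with 1 of 3 anticodons higher in hPAC under every scaling. Their median log2 ratio was -2.25, above 6.17% of matched lists, but the members went opposite ways, with both Gln anticodons higher in xPAC and Asn-GUU 5.39-fold higher in hPAC. The basic amino acids Lys, Arg and His held 19.0% and 26.6%, with 5 of 7 anticodons higher in hPAC on tRNA totals but 2 of 7 under either other scaling. Branched and hydrophobic amino acids, Val, Leu, Ile and Met, held 3.63% and 5.84%, with 8 of 11 anticodons higher in hPAC and 6 of 11 under either other scaling. Per listed gene copy the order turned here too, to 7.41% and 4.11%. Aromatic amino acids held 3.05% and 2.51%, and 7.56% and 4.89% per listed gene copy. The small or hydroxyl amino acids held 16.3% and 30.5%, with 12 of 17 anticodons higher in hPAC and 11 of 17 under either other scaling. The acceptors of queuosine, a modified wobble base, held 28.3% and 15.2%, with 2 of 4 anticodons higher in each library. The 8 anticodons whose first base, A, is converted to inosine held 8.30% and 9.62% of nuclear tRNA reads, with 5 of 8 higher in hPAC under every scaling. Tyrosine tRNA, an intron-containing class, held 0.852% and 0.722%, and 1.36% and 1.05% per listed gene copy. Among the lists fixed beforehand that were ranked against matched random lists, the long variable arm list stood highest and the amides lowest. The median log2 ratio of the others was above 84.4% of matched lists for small or hydroxyl, 73.2% for queuosine, 51.9% for inosine, 49.8% for basic, 39.4% for acidic, 31.0% for branched and hydrophobic and 22.3% for aromatic amino acids. Initiator methionine tRNA held 0.440% of hPAC tRNA reads over 8 genes, and none of the 7 Met genes listed in xPAC carried the initiator stem-loop; genes with 10 reads or fewer are not in that list.

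Mitochondrial tRNAs were listed in hPAC, where all 22 genes held 2.38% of tRNA reads (2.35 to 2.40). In xPAC every listed tRNA gene was treated as nuclear, without a search for mitochondrial ones. Whether the insect reference held the mitochondrial genome is not known, so the libraries cannot be compared on this point. Mitochondrial tRNA-Glu (TRNE, chromosome M, 14674 to 14742, minus strand) alone had 20039 reads (12669 RPM, reads scaled to 1000000 of the denominator), 69.0% of the mitochondrial tRNA reads. By reads it was the fifth highest single hPAC tRNA gene. That rank does not compare tRNAs, since nuclear families hold their reads over several copies, as TRE-CTC1 does with 138709 reads over 7 genes. Mitochondrial tRNA-Pro (TRNP, 15956 to 16023) had 2896 RPM and tRNA-His (TRNH, 12138 to 12206) 1249. The other mitochondrial tRNAs were lower, with TRNY next at 240 RPM and TRNW last at 2.53. The mitochondrial gene ND6 (14149 to 14673, minus strand), which encodes a respiratory complex subunit and directly adjoins TRNE, had 5744 reads, 3631 RPM. The mitochondrial rRNA RNR2 had 172 RPM.

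**Figure D3:**
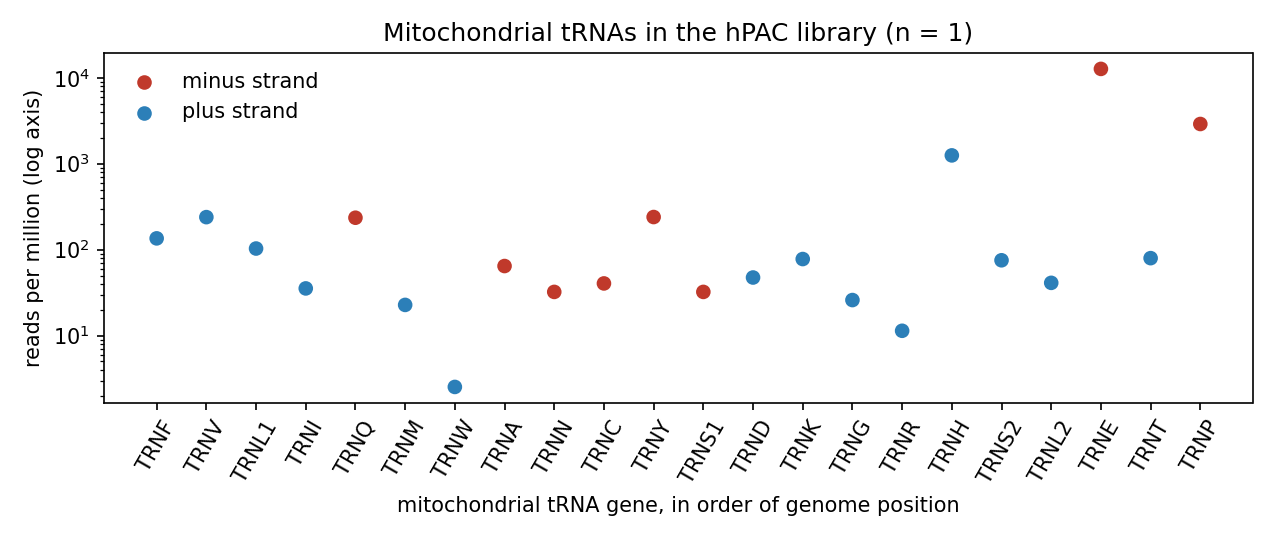
RPM (log axis) of each of the 22 mitochondrial tRNA genes in the 1 hPAC library, in order along the mitochondrial genome and coloured by strand. TRNE, TRNP and TRNH stand above the others at 12669, 2896 and 1249 RPM.

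Other small RNAs were rare in hPAC. The Y RNAs, partners of the Ro protein, had 118 reads together, 94 of them from RNY5. The 3 vault RNAs had 57 reads, the 3 listed 7SL genes (signal recognition particle RNA) 30, and 7SK, a regulator of transcription elongation, 9. RPPH1, the RNA of RNase P, which trims tRNA precursors, had 3 reads and RMRP 1. The spliceosomal RNAs RNU5B-1 and RNU5A-1 had 68 and 62 reads. The gene of the expressed channel, PACC1 (also TMEM206), was not listed in hPAC, so its transcript gave no check of the labels. Among lncRNAs, LOC107986586 (RPKM 16867), PRMT5-DT (RPKM 7607) and LINC00324 (RPKM 4929) had the highest values. The 10 lncRNAs with the highest RPKM each overlapped at least 1 listed tRNA gene on the same strand, so their values cannot be separated from tRNA reads with the deposited table.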

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

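The tests on denominators without the rRNA pseudogene, with listed widths or with recovered genes alone, and the correlations per gene copy and with unlisted anticodons, were chosen after the results were seen. The tRNA share of xPAC, 50.4%, was 56.6% without the most abundant feature, 76.7% with rRNA left out, 58.5% with unnamed genes left out and 91.9% with rRNA and the pseudogene beside the rRNA genes left out. The hPAC share, 77.3%, was 76.7%, 77.8% and 97.7% under the first 3 of these, 75.4% for cytosolic tRNA alone, 69.9% with the listed width for every gene and 96.7% over the genes whose reads were recovered. The hPAC share was the higher under each setting run on both libraries, but these settings do not settle the order. The most abundant feature was a pseudogene in xPAC and a tRNA gene in hPAC. With rRNA left out, the pseudogene beside the rRNA genes stayed in the xPAC denominator, and without it the xPAC share was 91.9%. A minimum of 10 reads and cytosolic tRNA alone left the xPAC share unchanged. Settings run on only 1 library cannot be set side by side. The xPAC tRNA-Asp share, 26.7%, was 14.7% without the most abundant tRNA gene, below the 24.7% of tRNA-Gln, and 24.4% as a mean per listed gene copy, above the 22.5% of tRNA-Gln. The hPAC tRNA-Glu share, 22.0%, was 19.4% and 24.5% under the same settings. With amino acids as the unit, the effective number was 9.22 in xPAC and 11.4 in hPAC. Per gene copy, the long variable arm list held 1.43% and 5.82%, in the same order as before, but the order of the libraries turned for the acidic list (30.7% and 33.8%) and for the branched and hydrophobic list (7.41% and 4.11%), and the aromatic list moved to 7.56% and 4.89%. The basic, amide, small or hydroxyl, queuosine and tyrosine lists kept their order. Orders per gene copy rest on unlike lists, since the lowest listed tRNA gene had 11 reads in xPAC and 0.5 in hPAC. The Spearman correlation between libraries, 0.535, was 0.480 without the most abundant anticodon of each, 0.423 per gene copy and 0.517 with unlisted anticodons at 0. A minimum of 10 reads removed nothing in xPAC or among shared anticodons, so it tests nothing there, and in hPAC it moved no value beyond counting error. Unnamed genes were protein-coding genes, lncRNAs and pseudogenes in xPAC, but database-numbered or unresolved genes in hPAC, so these settings differ. Each alternative scaling or denominator moved all anticodon ratios by 1 constant, and the 20 named ones were picked for their size, so their unchanged signs test nothing. No tRNA pseudogenes were listed, and the pseudocount was not run because reads were recovered. At these depths counting error, with reads taken as independent, is small beside the shifts between denominators. The causes of these shifts were not tested beyond what each setting leaves out. No paired analysis was possible because each group holds 1 library, and leaving out a replicate was likewise not possible.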

Other observations

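All tests in this part were chosen after the results were seen. Among hPAC snoRNAs, the box C/D genes (SNORD), which guide ribose methylation, held 11666 reads over 147 genes, and the box H/ACA genes (SNORA), which guide pseudouridylation, held 67 reads over 32 genes. SNORD34 led with 1023 reads, followed by SNORD18C with 720, SNORD31 with 506, SNORD43 and SNORD26 with 462 each and SNORD92 with 440. SNORA3A led the other class with 7 reads. MIR4521 (GRCh38 chromosome 17, 8186945 to 8187004, plus strand), with 361 of the 436 miRNA reads, shares its first 3 bases with the end of the tRNA gene TRS-GCT4-3 (8186866 to 8186947), which had 2638 reads. These genes were singled out after their values were seen.

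Anticodons were also grouped by their middle base, a grouping that was not among the lists fixed beforehand. All 4 bases were computed, a first set of tests was made on base A and on read placement among identical copies, and base U was then taken up in their place because it stood out more, so its prominence is partly a product of that search. Base U (Asp, Glu, Gln, Lys, His, Asn and Tyr) held 70.7% of xPAC and 46.2% of hPAC nuclear tRNA reads, base A 5.25% and 6.40%, base C 13.7% and 28.5%, and base G 10.4% and 18.8%. Shares of listed genes depend on the floor of each list, 11 reads for a tRNA gene in xPAC and 0.5 in hPAC. The share of reads over the share of listed nuclear genes was 1.72 and 1.64 for U, 0.316 and 0.242 for A, 0.680 and 1.16 for C, and 0.468 and 0.90 for G.

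These ratios describe the pattern and do not test an explanation of it. For base U, the xPAC ratio was 1.63 without Asp-GUC, which argues against Asp-GUC alone but leaves Gln in place. In hPAC it was 1.43 without Glu-CUC, under the bound of 1.5, itself set after values were known, so a dominant anticodon stays open there. Members went both ways. By amino acid, the xPAC ratio was 3.91 for Asp, 3.61 for Gln, 1.23 for Lys and 1.02 for Glu. It was 0.218 for Tyr, 0.131 for His and 0.124 for Asn. With mitochondrial tRNA counted, the hPAC ratio was 5.67 for Glu, 2.54 for His, 2.15 for Asp and 1.02 for Lys. It was 0.758 for Gln, 0.351 for Asn and 0.243 for Tyr. Base U as a shared trait was therefore not shown. GC content showed no trend with reads over the 129 distinct xPAC sequences (Spearman correlation -0.0186, across sequences that are not independent replicates). The makeup of the cells' own tRNA pools, base modifications left after demethylation and a preference of the channel or its purification stay open and were not tested.

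In hPAC, TRNE and TRNP led the mitochondrial tRNAs, as glutamate and proline led the nuclear ones. The 6 other minus-strand tRNAs lay between 32.2 and 240 RPM. Whether a shared minus-strand precursor, which also carries ND6, plays a part was not tested. A shared order of amino acids in the mitochondrial and nuclear pools was tested as a hypothesis across 20 amino acids, which are not independent replicates. The Spearman correlation was 0.257 (permutation p = 0.275, adjusted p = 0.275 over 2 relations) and the Pearson correlation of log2 reads 0.387 (permutation p = 0.0918, adjusted p = 0.184), two-sided. Without the 2 amino acids farthest from the mitochondrial median, Glu and Pro, the Pearson correlation was -0.0116 and the Spearman correlation -0.0196. The lead of Glu and Pro had raised the hypothesis, so a test that includes them is not independent of it. Arg and Gly, ranked 3 and 4 in the nuclear pool, ranked 19 and 17 in the mitochondrial one. No relation was shown, and the hypothesis was neither borne out nor excluded.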
